A study of Mus musculus with 2 samples.

How the data were processed

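Single-cell RNA sequencing was done on dentate gyri of postnatal day 2 mice. One library came from hGFAP-Cre;Kdm6bF/F mice (called the KO library) and 1 from littermate controls, with 2 animals per genotype pooled in each library, per the labels. hGFAP-Cre is a transgene that expresses Cre recombinase in radial glia and so reaches the neurons and glia that descend from them. Tissue was dissociated with papain, and droplet libraries of the 3′ ends of transcripts were made with the 10x Genomics assay, aiming at 2500 cells per genotype, per the labels' protocols. The deposited values are whole-number UMI counts per gene and barcode, not normalized. Cell Ranger 3.0.2, Seurat 3 and the mm10 build are named in the submitters' processing notes, with no role stated, and the tables list 31053 genes. No table of cell types was used here, so cell types were rebuilt from the counts.

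Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. That left 3029 of 3555 barcodes in the control library and 1967 of 2292 in the KO library. Scrublet, run in scanpy 1.11.5, marked 15 and 10 barcodes at its own threshold (0.422% and 0.436%), which is too few to have worked, so the highest-scoring 0.8% per 1000 barcodes of each library were removed. This took out 71 and 34 of the barcodes that had passed. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering (leidenalg 0.10.2, resolution 1) of both libraries together. Members of the gene lists described next were left out of the variable genes. Clusters were named by 18 marker lists. A cluster had to show at least 3 markers of a type, each detected in at least 10% of its cells and at least 1.5-fold above the other clusters, and no other type could hold more markers among its 10 leading genes, or as many with more detected markers. Of 26 clusters, 5 stayed unnamed and are given by number. The rule for ties left out clusters 5 and 18. Cluster 5 had 6 detected intermediate progenitor markers but more detected markers of radial glia/neural stem cells. Names such as astrocyte-like rest on these markers alone.

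UMIs were summed per library and class. Ratios are log2 of CPM (UMIs of a gene over all UMIs of the class), KO over control, with 0.5 UMI added to each sum. Exact Poisson intervals were used for sums, exact conditional binomial intervals for ratios and exact Clopper-Pearson intervals for shares, all at 95% and all covering counting error only. With 1 library per genotype no test between genotypes can be made, so no p-value is given and no difference has a replicate check. The values compare these 2 libraries, not the genotypes. Where 1 library had 0 counts, its limit was set at 3 counts. 21 gene lists were fixed before the data were examined, as were the markers, filters, named-gene rule and 38 alternatives. A list's median was taken over members with at least 20 UMIs across both libraries, and its place among 10000 random lists of the same size and matched mean expression is given as a description of these libraries. Counting error of a median came from 1000 Poisson redraws.

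The genes named for the radial glia/neural stem cell-like class are the 12 most above and the 12 most below in the KO library. The granule neuron-like class was also planned as a main class, but with 36 control and 2 KO cells it lay under the minimum of 50 cells per library. For the intermediate progenitor-like and neuroblast-like classes they are the 6 most above and the 6 most below. Ranking used the bound of the ratio interval nearest to 1 among genes with at least 50 UMIs. Mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and predicted gene models were left out of the ranking. Up to 4 members of each list spoken of and 10 genes fixed by name were added. Some genes that this rule takes are not reported here. Genes named outside this rule were chosen after their values were seen: Prm2, Tnp1, Tnp2, Neurod6, Cdkn2a and Cdkn2b. For shares of cells with a UMI, cells were thinned to 2000 UMIs, and 202 control and 157 KO cells below that depth were left out.

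Class sizes can be set by the genes that define a cluster when those genes differ between libraries. The cells were therefore clustered again without 772 genes whose ratio interval lay beyond 1.5-fold within a cluster, a step chosen after the data were seen. Other alternatives changed filters, doublet removal, clustering, scaling, depth, minimum counts and the cells used, and 13 were added after the data were seen. In 1 of these the UMIs of the KO library were drawn at random down to the control library's median depth before filtering and clustering, with the doublet removal kept. Scaling factors came from edgeR 4.0.16 in R 4.3.3. The ratio step was tested on simulated Poisson counts with 200 genes altered per class. Such counts follow the model of the intervals, so this checks the computation and not spread between cells, clusters or animals. In the radial glia/neural stem cell-like class, over 4783 genes, simulated folds of 1.5 and 3 came back as 1.51 and 3.004, and 93.0% and 96.0% of intervals held the true value. Gene positions are 1-based and come from GENCODE release M21 on GRCm38, the assembly also called mm10. Analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.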

Results

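Dentate gyrus cells of postnatal day 2 mice were profiled in 1 control library and 1 library from mice lacking Kdm6b in the hGFAP-Cre lineage (the KO library). The comparison asks how loss of the H3K27 demethylase KDM6B bears on hippocampal neural stem cells and their progeny. After filtering, the control library held 2958 cells with 31625208 UMIs (median 7347.5 UMIs and 2917 genes per cell). The KO library held 1933 cells with 25533397 UMIs (median 9318 UMIs and 3386 genes). Neither genotype has a second library, so every interval covers counting error only. Sex differed as well: 33.4% of control cells (95% interval 31.7 to 35.2%) had Y-linked UMIs without Xist, against 0 of 1933 KO cells (up to 0.191%), so genotype and sex were partly confounded.

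Kdm6b UMIs were at the same level in both libraries over all cells and lower in the KO library in several neural classes. Kdm6b (ENSMUSG00000018476; chromosome 11, 69398508 to 69413675, minus strand) had 1832 UMIs in the control library and 1471 in the KO library, or 57.9 CPM (55.3 to 60.6) and 57.6 CPM (54.7 to 60.6), a log2 ratio of -0.01 (ratio interval 0.928 to 1.07). In intermediate progenitor-like cells it was lower in the KO library, 82 against 16 UMIs (-0.95; ratio interval 0.276 to 0.872). In astrocyte-like cells it was also lower, 78 against 9 UMIs (-0.97). The neuron clusters without a name, 0 and 1, gave -0.79 and -0.84, and cluster 5, with mitotic genes, gave -0.93. Neuroblast-like (-0.18), ependymal-like (-0.12), pyramidal neuron-like (-0.03) and GABAergic neuron-like cells (0.04) had intervals that held 1. Neuroblast cluster 9 was lower (-0.87), while neuroblast cluster 2 was at 0.19 with an interval that held 1. Pyramidal clusters 8 (-0.96), 10 (-0.42) and 19 (-0.56) were all lower, with intervals that held 1 in clusters 10 and 19. Cluster 10, with the highest Kdm6b CPM of them, had 24 control and 164 KO cells, so the class value also reflects the mix of clusters. Radial glia/neural stem cell-like cells had 36 and 61 UMIs (0.36), with an interval that held 1 (0.841 to 2.00). Endothelial-like cells, which lie outside the radial glial lineage, had 520 and 586 UMIs (0.29). They were a larger part of the KO library, so the value over all cells also depends on class sizes. The flanked exons are not given in the sources used here, and a 3′ tag outside them would still be counted, so Kdm6b UMIs do not check the labels. Averaging the fraction per cell instead of summing UMIs moved the value over all cells to 0.27.

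**Figure D1:**
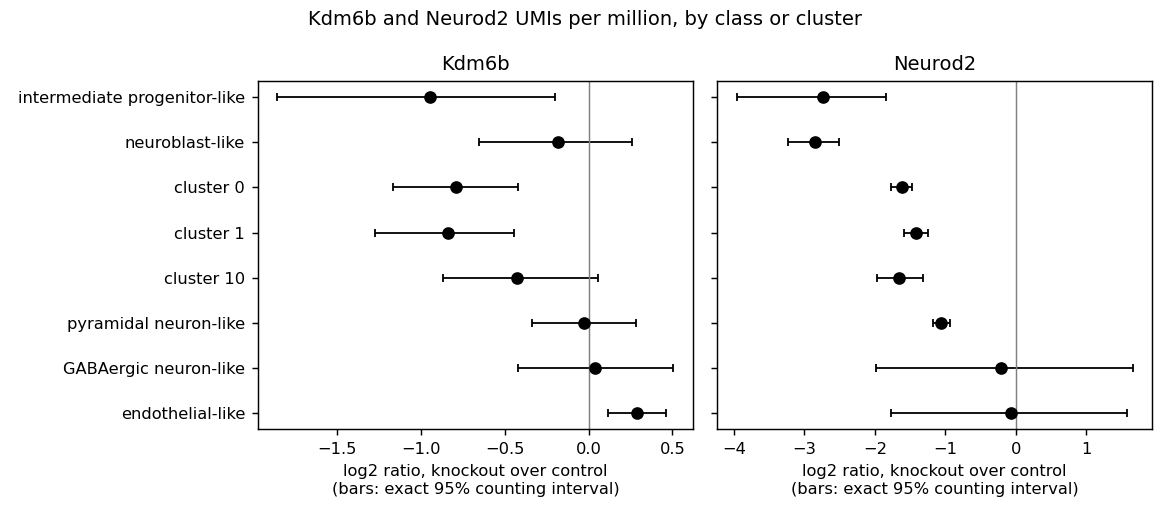
Log2 ratio (x axis, KO over control) of Kdm6b and Neurod2 CPM in classes and clusters (y axis); points are ratios and bars exact 95% counting intervals. Kdm6b lay at -0.95 in intermediate progenitor-like cells and 0.29 in endothelial-like cells, while Neurod2 lay at -2.85 in neuroblast-like cells.

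Intermediate progenitor-like and neuroblast-like cells made up a smaller part of the KO library. Radial glia/neural stem cell-like cells were 5.21% of control cells (154 cells; 4.43 to 6.07%) and 7.19% of KO cells (139 cells; 6.08 to 8.43%; log2 ratio 0.47). Among cells with Xist and no Y-linked UMI they were 6.35% (5.09 to 7.81%) and 7.20% (6.06 to 8.49%), a log2 ratio of 0.18 with overlapping intervals. The 2 clusters of the class went opposite ways: cluster 11 was 2.27% and 6.10% (ratio interval 1.98 to 3.69) and cluster 17 was 2.94% and 1.09% (0.218 to 0.600). Intermediate progenitor-like cells, which divide to give neuroblasts, were 6.22% (184 cells) and 3.31% (64 cells; log2 ratio -0.90). Neuroblast-like cells were 14.7% (434 cells) and 9.05% (175 cells; -0.69), but 4.53% and 3.36% with 4000 variable genes in the clustering, where the ratio interval held 1 (0.543 to 1.01). Of its clusters, cluster 2, led by Gal and Prox1, was 9.74% and 6.31% (-0.62), and cluster 9 was 4.94% and 2.74% (-0.84). The leading genes of cluster 2 hold as many granule neuron markers (Prox1, Sema5a) as neuroblast markers (Gal, Igfbpl1). Those of cluster 9 hold as many pyramidal neuron markers (Grp, Meis2) as neuroblast markers (Sema3c, Igfbpl1). Astrocyte-like cells were 8.79% and 3.41% (-1.36), but 9.50% and 7.69% without the filters on genes, UMIs and mitochondrial share and 9.94% and 7.40% at a clustering resolution of 0.5. Cajal-Retzius cell-like cells were 4.36% and 1.66% (-1.38), and oligodendrocyte lineage-like cells 5.04% and 2.43% (-1.04), or 4.85% and 1.27% with a stricter filter. Ependymal-like cells, which line the ventricle, were 3.04% of control and 8.23% of KO cells (1.43), but 6.54% and 8.58% without those filters. Endothelial-like cells were 7.84% and 12.1% (2.64% and 6.16% at resolution 2), and mural-like cells 0.507% and 2.74%. GABAergic neuron-like cells were 5.07% and 8.07% (0.67). Cluster 5, led by the mitotic genes Esco2, Pbk and Spc25 and left unnamed, was 6.90% and 3.72% (-0.88). It had more detected radial glia/neural stem cell markers than intermediate progenitor markers. Counted with the radial glia/neural stem cell-like class, it would put the control share above the KO share. Cluster 18, unnamed with ependymal and astrocyte markers, was 0.811% and 3.67%, which goes the other way. With KO UMIs thinned to the control depth, a cluster also led by Pcp4l1 and Krt15 took the radial glia/neural stem cell name. It held 24 control and 67 KO cells. Whether the radial glia/neural stem cell-like share is higher in the KO library therefore depends on which unnamed clusters are counted with it.

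Several clusters had leading genes that differed between libraries, among them Neurod1 in the intermediate progenitor-like cluster, Aqp4 in the astrocyte-like cluster and Prm1 in radial glial cluster 11. When such genes were left out of the clustering, radial glia/neural stem cell-like cells were at 0.37 (ratio interval 1.03 to 1.62), again as the sum of clusters that went opposite ways (57 control and 107 KO cells in 1, and 116 and 39 in the other, led by Pdlim3 and Thrsp). In that clustering astrocyte-like (8.92% and 3.83%), neuroblast-like (9.63% and 6.26%) and oligodendrocyte lineage-like cells (4.53% and 1.55%) were lower. Ependymal-like cells were then 3.08% and 8.23%, and endothelial-like cells 7.84% and 12.1%. No cluster then took the intermediate progenitor name. Of the 248 intermediate progenitor-like cells, 223 fell in 1 cluster led by Tac2 and Eomes, which held 178 control and 69 KO cells, 6.02% and 3.57% (-0.75; ratio interval 0.443 to 0.787). Pyramidal neuron-like cells were 7.54% and 15.6% at first but 10.6% and 11.5% in that clustering, and granule neuron-like cells were 1.22% and 0.103% at first but 12.1% and 10.3% (-0.23). The later value comes from a cluster of 323 control and 198 KO cells, led by Hs3st4 and Fxyd7, that took the granule neuron name with a mean marker log2 fold of -0.42, while the cluster led by Calb1 and C1ql3 still held 36 and 2 cells. Only 2 KO cells were granule neuron-like at first, so genes were not compared in that class. Shares were also taken among the 4 lineage classes alone (radial glia, intermediate progenitor, neuroblast and granule neuron), without cluster 5. Among these, radial glia/neural stem cell-like cells were 19.1% (16.4 to 21.9%) and 36.6% (31.7 to 41.6%). Intermediate progenitor-like cells were then 22.8% (19.9 to 25.8%) and 16.8% (13.2 to 21.0%), and neuroblast-like cells 53.7% (50.2 to 57.2%) and 46.1% (41.0 to 51.2%), with overlapping intervals.

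**Figure D2:**
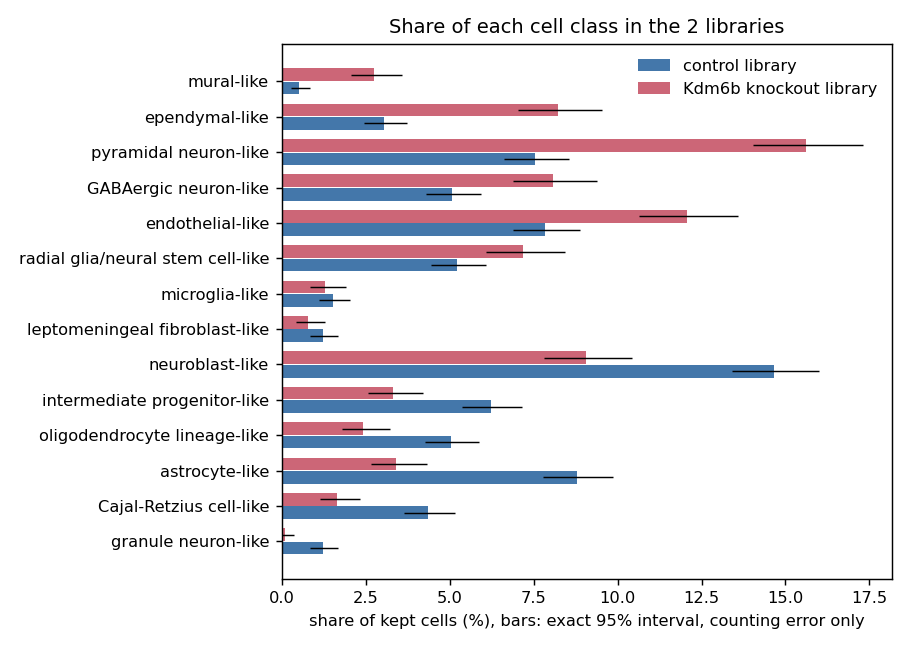
Share of kept cells (x axis, percent) in each cell class (y axis) in the control and KO libraries; lines are exact 95% intervals for counting error. Radial glia/neural stem cell-like cells were 5.21% and 7.19%, and neuroblast-like cells 14.7% and 9.05%.

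In radial glia/neural stem cell-like cells the median of the Notch pathway list lay higher in the KO library, and those of the cholesterol synthesis and S phase lists lay lower. Mitochondrial UMIs were 2.81% of the UMIs of the class in the control and 3.42% in the KO library (ratio interval 1.19 to 1.24), and ribosomal protein UMIs were 9.42% in both. Different clusters held most of this class: cluster 17 (led by Tfap2c, Hopx and Thrsp) had 87 of 154 control cells and cluster 11 had 118 of 139 KO cells. The Notch list had a median log2 ratio of 0.45 over 12 members, with 3 higher by at least 1.5-fold and 0 lower (percentile 99.97 among random lists), against 0.46 in cluster 11, 0.34 in cluster 17 and 0.06 in endothelial-like cells. Hes1, a Notch target that represses neurogenesis, was higher at 1.41, Notch2 at 1.11, Hes5 at 0.46 (-0.06 among the 15 control and 18 KO cells with fewer than 3 cell cycle UMIs after thinning, called non-cycling) and Nrarp at 0.34 (-0.50 in cluster 17). Hes1 was higher in cluster 11 (1.19) and cluster 17 (0.72) and also in endothelial-like cells (0.95). In the stem cell maintenance list more members were lower by at least 1.5-fold (5) than higher (3) and 22 of 30 lay within 1.5-fold, with a median of 0.26 (percentile 99.99). The median was 0.14 and 0.16 in the 2 clusters, 0.16 over all cells, 0.18 in endothelial-like and 0.59 in ependymal-like cells. Among its members Nfia was at 0.58 (-0.11 among non-cycling cells) and Sox2 at 0.45, while Hopx was at -1.05. Hopx leads cluster 17 and Hes5 cluster 11, but both were left out of the genes used for clustering.

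In the same class the cholesterol synthesis list had a median of -0.51 over 18 members, with 6 lower by at least 1.5-fold and 0 higher (percentile 0.01), with -0.42 in cluster 11 (7 of 18 lower, 1 higher) and -0.55 in cluster 17 (7 of 15 lower, 0 higher). Over all cells the median was -0.23 (percentile 0), with all 19 members within 1.5-fold. It was -0.29 in neuron cluster 0, -0.23 in intermediate progenitor-like, -0.18 in astrocyte-like, -0.08 in endothelial-like and -0.03 in neuroblast-like cells. Cyp51 was at -1.06, Mvd at -1.10, Msmo1 at -0.80 and Idi1 at -0.83 (0.36 among non-cycling cells). S phase genes had a median of -0.69 over 29 members (15 lower, 1 higher), -0.06 in cluster 11, -0.48 in cluster 17 and -0.39 in endothelial-like cells, and 1.47 among non-cycling cells, which were picked by these genes. Mcm6, a subunit of the replicative helicase, was at -2.77, Mcm3 at -1.92 (1.39 among non-cycling cells), Mcm4 at -1.26 and Nasp at -0.94. Interferon response genes had a median of 0.88 over 7 members (4 higher, 0 lower), with Ifitm3 at 2.47, H2-K1 at 0.88, H2-D1 at 0.56 and B2m at 0.50 (ratio interval 0.989 to 2.08). The median was 0.59 in cluster 11, 0.17 over 2 members in cluster 17 and -0.35 in endothelial-like cells, and H2-K1 (-0.41) and H2-D1 (-3.38) were lower in cluster 17.

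Other lists in this class differed between the clusters or lay nearer to 0. The neuronal differentiation list was at -0.36 (7 of 21 members lower, 0 higher), but -0.038 in cluster 11 and 0.0425 in cluster 17. Its named members were Stmn2 (-1.11), Stmn3 (-1.07), Tubb3 (-0.82) and Zbtb20 (0.29, but -0.10 among non-cycling cells). The extracellular matrix list was at 0.49 but 0.03 and -0.26 in the 2 clusters, with Nid1 at 1.69, Itgb5 at 1.83, Gpc4 at 1.17 and Timp2 at 0.93 (-0.47 in cluster 17). The glycolysis and hypoxia list was at -0.30 in this class and -0.31 in endothelial-like cells. Medians were 0.20 for G2/M phase (-0.13 with each cell weighted alike), 0.12 for astrocyte maturation (-0.34 in cluster 11), 0.12 for CDK inhibitors, 0.11 for dissociation and immediate early genes (-0.18 in cluster 11), 0.09 for the oligodendrocyte programme, 0.07 for Polycomb and H3K27 enzymes (1 higher, 4 lower), -0.01 for the BMP pathway, -0.09 for the Hedgehog pathway, -0.10 for the p53 response, -0.15 for migration signalling and -0.20 for the Wnt pathway. Within the BMP list Id1 was at -1.33 (0.59 in cluster 11) and Id2 at -1.24 while Bmp6 was at 1.46. Polycomb-silenced developmental regulators had 0 members with enough UMIs in any of the 3 main classes, and 15 members over all cells, of which 3 were higher by at least 1.5-fold, 5 lower and 7 within (median 0.27). Xist was at 0.87 and the sex-linked list at -2.44 over 2 members.

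Among single genes, Prm1, which encodes a sperm protamine, stood furthest above in radial glia/neural stem cell-like cells, with 1 control and 2689 KO UMIs (ratio interval 367 to 80875). It is also a leading gene of cluster 11 and was among the genes used for clustering. Others most above were Ifitm3, Ston2 (2.38), Hipk1 (2.01), Lgals1 (1.96), Tceal3 (1.77), Hist1h2ap (1.72), Kcnk2 (1.54), Hes1, Crip1 (1.40) and Mt3 (1.21). Kcnk2 was at -2.04 and Hist1h2ap at -0.0229 in cluster 17. Dbx2, a homeobox gene, stood furthest below, with 55 and 2 UMIs (-4.87; ratio interval 0.00327 to 0.105), and was lower in cluster 11 (-4.82) and cluster 17 (-2.67). Sparcl1 (-1.63), Gadd45g (-1.79), Nrn1 (-2.35), Col9a3 (-2.25) and Rgs5 (-2.16) were lower in both clusters, and Lhx9 (-2.72) was at 0.96 in cluster 11. Pdlim3 (-3.23), Rbp4 (-3.59), Tesc (-2.73) and Frzb (-2.94), also among the 12 most below, lead cluster 17. The first 3 were lower in both clusters, and Frzb was at 0.23 in cluster 11. Of the genes fixed by name, Neurog2, a proneural factor, had 11 and 1 UMIs (ratio interval 0.00161 to 0.476), Prox1 -0.36, Dcx -0.79, Ezh2 -0.13 and Kdm6a 0.36. Eomes had 3 and 1 UMIs (ratio interval 0.00483 to 3.16).

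In intermediate progenitor-like cells 8 of 31 measured neuronal differentiation genes were lower by at least 1.5-fold in the KO library and 0 were higher. The list's median was -0.26 (percentile 0), against -0.23 in endothelial-like and -0.38 in ependymal-like cells. Neurod2, a bHLH factor of neuronal differentiation, was lower at 163 against 9 UMIs (-2.73), as were Rbfox1 (51 and 3 UMIs; ratio interval 0.0305 to 0.472), Stmn2 (-1.38) and Neurod1 (-0.81), which leads their cluster but was left out of the genes used for clustering. The stem cell maintenance list was at 0.32 over 18 members (5 higher, 1 lower; percentile 99.81), with Hes5 at 0.67, Lhx2 at 0.38, Nfib at 0.32 and Nfix at 0.25. The median of that list was 0.16 over all cells, 0.18 in endothelial-like and 0.44 in pyramidal neuron-like cells. The astrocyte maturation list was at 0.25 over 14 members (5 higher, 0 lower; percentile 98.7). Mitochondrial UMIs were 3.06% and 3.84% of the UMIs of this class (ratio interval 1.23 to 1.28) and ribosomal protein UMIs 11.8% and 13.3% (1.12 to 1.14), against 3.28% and 3.50%, and 16.8% and 16.5%, in endothelial-like cells. Also lower were Gadd45g (-1.59), Lhx9 (-1.49) and Stmn4 (-1.40). Higher were Ankrd11 (1.52), AC149090.1 (1.37, and 2.19 in endothelial-like cells), Tmem2 (1.20), Apoe (1.12) and the putative demethylase gene Jmjd1c (1.02). Prm1 had 0 control UMIs and 185 KO UMIs, at least 160-fold higher against a limit of 3 counts (ratio interval from 129). Eomes, which leads their cluster and was used to form it, was at 0.33, Neurog2 at 0.42, Prox1 at -0.27 and Ezh2 at -0.35. Kdm6a, the X-linked paralogue of Kdm6b, was at 1.19 with 16 and 14 UMIs. The sex difference between the libraries may bear on this X-linked gene. Dcx, with 385 and 148 UMIs, had a ratio interval of 0.819 to 1.21. Sox2 was at 0.06, and Hopx had 4 and 1 UMIs (ratio interval 0.0132 to 6.55).

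Neuroblast-like cells of the 2 libraries differed little in the neuronal differentiation list as a whole, yet differed in Neurod2. Mitochondrial UMIs were 3.66% and 4.02% and ribosomal protein UMIs 10.9% and 11.9% of the UMIs of the class. The list was at 0.01 over 35 members (2 higher, 3 lower), and Prox1 (0.02) and Dcx (0.09) had intervals that held 1. Neurod2 (chromosome 11, 98325415 to 98329648, minus strand) had 958 control and 70 KO UMIs, or 548 and 75.5 CPM (-2.85; ratio interval 0.106 to 0.176). Within the same list Neurod1, which with Prox1 leads cluster 2 but was not used for clustering, was at -0.59, Elavl4 at -1.38 and Nrgn at 0.95. Cck (-2.80), Syndig1 (-1.64) and the immediate early gene Ier2 (-1.35) were also lower. Car10 (3.81), Chodl (2.19), Ncam2 (2.01), Rit2 (1.93), AC149090.1 (1.89) and Meg3 (1.34) were higher. Alas2 (57 and 0 UMIs, at least 10.1-fold lower in the KO library against a limit of 3 counts; ratio interval up to 0.126) and Car2 (-2.79) are red blood cell genes, and 3 haemoglobin-rich control barcodes held 56 of the 57 Alas2 UMIs. The Wnt pathway list was at -0.56 over 8 members (1 higher, 2 lower), but 0.0918 over members with at least 100 UMIs. Ezh2 was at -0.54, Kdm6a at 0.16, Neurog2 at 0.24, Eomes at -0.67, and Sox2 had 15 and 4 UMIs. Hopx had 2 and 1 UMIs (ratio interval 0.0160 to 18.1).

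Over all cells 11 of 38 S phase genes and 17 of 53 G2/M phase genes were lower by at least 1.5-fold in the KO library and 0 were higher, with medians of -0.44 and -0.42. Cluster 5, with mitotic genes, was 6.90% of control and 3.72% of KO cells, while within it the S phase median was -0.0057 and the G2/M phase median -0.16. In ependymal-like cells the G2/M phase median was 0.22. With at least 3 UMIs of 91 S and G2/M genes after thinning, 73.7% of control and 69.8% of KO cells counted as cycling (96.0% and 94.8% unthinned). The measure was saturated, since 59.3% and 56.0% of GABAergic neuron-like cells, which do not divide, also counted. With the 69 genes below 10 CPM in that type, chosen after the data were seen, the shares were 23.7% (22.2 to 25.4%) and 22.0% (20.1 to 24.0%), or 57.5% and 61.9% unthinned. This choice sets the share of GABAergic neuron-like cells near 0. In pyramidal neuron-like cells, which do not divide and did not enter the choice, 1.56% (0.323 to 4.50%) and 2.77% (1.20 to 5.38%) then counted, and 42.2% and 45.7% unthinned. Ependymal-like cells counted at 58.3% and 67.6%, or 49 of the 654 control and 100 of the 390 KO cells that counted. Whether ependymal-like cells divide was not checked, so the measure may count them wrongly. They were a larger part of the KO library, so the shares over all cells also depend on class sizes. Without them the KO share over all cells would lie further below the control share. Radial glia/neural stem cell-like cells were then at 31.2% and 24.0% (48.1% and 53.2% unthinned), intermediate progenitor-like cells at 25.3% and 25.9% (50.5% and 51.6%), and neuroblast-like cells at 6.78% and 3.05% (27.9% and 32.0%). Median depths were 3823 and 5479 UMIs in radial glia/neural stem cell-like cells, 11252 and 13451.5 in GABAergic neuron-like cells and 9707 and 9942.5 in pyramidal neuron-like cells.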

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

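Predictions for all tests of explanations in this part were written after the result was seen, except that for sex on Neurod2. Its setting, cells with Xist and no Y-linked UMI, was still chosen after the data were seen. The differences between cell types listed first were not tested, since each library gives 1 value per class.

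Some genes lay on opposite sides of 1 in a neural class and in endothelial-like cells, with both counting intervals leaving out 1. Kdm6b was at -0.95 in intermediate progenitor-like cells and 0.29 in endothelial-like cells. In radial glia/neural stem cell-like cells Ifitm3 was at 2.47 and Sparcl1 at -1.63, against -0.46 and 0.22 in endothelial-like cells. Apoe was at 1.12 in intermediate progenitor-like cells and -0.25 in endothelial-like cells. Alas2, with 57 control and 0 KO UMIs, was at -5.93 with the added 0.5 UMI in neuroblast-like cells and 0.58 in endothelial-like cells; 3 control barcodes rich in haemoglobin carried 56 of its 57 UMIs. A signal also appeared outside the cells used: Prm1 had 271 CPM (348 UMIs) in the 359 KO barcodes left out by the filters and 0 UMIs (up to 1.95 CPM) in the 597 left out of the control library.

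Prm1 UMIs numbered 11087 in the kept cells of the KO library and 10 in those of the control library. Free RNA from other cells is argued against, because Prm1 CPM was 552-fold higher in radial glia/neural stem cell-like than in endothelial-like cells of the KO library (interval 385 to 819). An active protamine locus or germ cell RNA is argued against too, because Prm2, Tnp1 and Tnp2 had 0 UMIs in kept KO cells. That is a limit of 0.0271% of the Prm1 UMIs. A Cre transgene that carries a Prm1 sequence stays open as a hypothesis. Of the Prm1 UMIs in kept KO cells, 98.4% were in glial, ependymal, oligodendrocyte and progenitor clusters, which held 32.0% of those cells. That restates the pattern to be explained, so it does not test the hypothesis. In thinned cells Prm1 was seen in 96.7% of radial glia/neural stem cell-like and 1.46% of endothelial-like KO cells (99.3% and 8.15% unthinned; median depths 5479 and 20077 UMIs).

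Neurod2 was lower in neuroblast-like cells (-2.85), cluster 0 (-1.62), cluster 1 (-1.41) and pyramidal neuron-like cells (-1.06; mostly cluster 8 in the control and cluster 10 in the KO library) of the KO library. The other 34 members of the neuronal differentiation list had a median of 0.0146 (-0.0540 to 0.0545) in neuroblast-like cells, so the list had no shared fall. It mixes genes of early and late neurons, whose shifts could cancel in a median. Fewer late cells within the class thus cannot be judged from it. Neurod2 lies 28.93 Mb from Kdm6b on chromosome 11. Car10, among the genes most above in neuroblast-like cells, lies 23.7 Mb from Kdm6b on the same chromosome. The other genes most above or below in that class are not on chromosome 11. Whether a linked stretch bears on both genes was not tested. A single linked variant acting alike in every cell type would give like Neurod2 ratios, but those of neuroblast-like cells and cluster 1 differed by -1.44 in log2. Their counting intervals lay apart, but spread between animals is not covered, so such a variant is not decided on. Sex as the whole cause is argued against by the ratio among cells with Xist and no Y-linked UMI, -2.85 (ratio interval 0.105 to 0.179). The control cells among these may come from 1 of the 2 pooled animals, so a difference between animals is not covered. Fewer late cells within the class, a linked variant, alike in every cell type or not, and loss of KDM6B all stay open. No test here decides between them.

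Intermediate progenitor-like cells had a smaller share in the KO library (-0.90). Sex as the whole cause is argued against, as the log2 ratio was -1.14 among cells with Xist and no Y-linked UMI (ratio interval 0.320 to 0.631). The control cells in this comparison may come from 1 of the 2 pooled animals, so spread between animals is not covered. Greater depth in the KO library as the whole cause is argued against by a value of -0.97 (0.361 to 0.702) after KO UMIs were thinned, which brought the KO median from 9318 to 7584 UMIs beside 7347.5 in the control, and the cells were clustered again. Different tissue taken in the dissections stays open: mural cells per endothelial cell, which the lineage of the Cre should leave alone, were 3.52-fold higher in the KO library (1.95 to 6.72). That ratio rests on 15 control and 53 KO mural-like cells and does not show which region was taken. Loss of KDM6B stays open beside different tissue.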

How the results depend on the processing

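Settings that restrict cells to 1 radial glial cluster, to cells with Xist and no Y-linked UMI, to cells with at most 1% haemoglobin UMIs or to a depth, the clustering without differing genes and the thinning of KO UMIs to the control depth were chosen after the data were seen. Changes of sign were counted only where the main counting interval left out a log2 ratio of 0. Other values of opposite sign were counted as within or beyond the interval. Of 3105 values under planned settings, 2872 stayed within the counting interval, 215 moved beyond it and 18 changed sign by that rule. Of 894 under added settings the numbers were 757, 118 and 19. Single genes gave 2432 of the planned values. Settings that change the minimum count cannot alter a single gene's ratio, so those values were within by construction and the total overstates stability. List medians gave 489 within, 56 moved and 4 changed of 549 planned values, and shares 98, 21 and 0 of 119. Restricting to cells with Xist and no Y-linked UMI gave 297 within, 25 moved and 0 changed in sign by that rule. The radial glia/neural stem cell-like share, within its wide interval, was then at 0.18 in place of 0.47, with overlapping share intervals. The neuronal differentiation median in intermediate progenitor-like cells ranged from -0.43 to -0.23 and their share from -1.33 to -0.43 over planned settings. No paired analysis was possible because each genotype has 1 library and no test was made. The cause of the values below was not tested, except where said. Depth limits genes under 20 UMIs, while the granule neuron-like class is limited by its 2 KO cells.

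Among the 4 lineage classes alone, the log2 ratio of the share was 0.94 for radial glia/neural stem cell-like, -0.43 for intermediate progenitor-like and -0.22 for neuroblast-like cells. With 4000 variable genes the neuroblast-like share was at -0.42 with a ratio interval that held 1 (0.543 to 1.01), and at 0.021 among the lineage classes. The astrocyte-like share was at -0.30 without the cell filters and -0.42 at resolution 0.5, and the ependymal-like share at 0.39 without the cell filters. The granule neuron-like share was at -0.37 without the cell filters, -0.68 with the stricter filter, -1.37 with no doublets removed, -0.77 with 4000 variable genes, -0.77 at resolution 0.5, -0.35 with list members kept and -0.23 without differing genes, where another cluster (323 and 198 cells) took the name and the cluster led by Calb1 and C1ql3 stayed at 36 and 2 cells. The intermediate progenitor-like share has no value with the stricter filter, with list members kept or without differing genes, because no cluster took that name. Kdm6b over all cells was at 0.27 with each cell weighted alike, which also put the G2/M phase median of radial glia/neural stem cell-like cells at -0.13.

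Thinned cells gave stem cell maintenance medians of 0.44 in radial glia/neural stem cell-like, 0.17 in intermediate progenitor-like and 0.38 in neuroblast-like cells, a neuronal differentiation median of -0.18 in radial glia/neural stem cell-like cells, Cdh2 at -0.26 in intermediate progenitor-like cells, and Suz12 at -0.14 and Mtf2 at 0.15 in neuroblast-like cells. A minimum of 100 UMIs gave 0.36 for stem cell maintenance and -0.12 for neuronal differentiation in radial glia/neural stem cell-like cells and 0.0918 for the Wnt pathway in neuroblast-like cells, while no minimum gave 0.31 for stem cell maintenance in neuroblast-like cells. Classes from the library-centred clustering gave 0.55 for stem cell maintenance and -0.43 for neuronal differentiation in intermediate progenitor-like cells, and Nbl1 at -0.26 and Fdps at -0.0193 in neuroblast-like cells.

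In non-cycling radial glia/neural stem cell-like cells (15 and 18 cells) the S phase median was 1.47, where the choice of cells by these genes acts on the value, Mcm3 was at 1.39, Hist1h2ap at -0.20, Nfia at -0.11, Zbtb20 at -0.10, Hes5 at -0.0599 and Idi1 at 0.36. Non-cycling intermediate progenitor-like cells gave Junb at -0.83, and non-cycling neuroblast-like cells the Wnt pathway at 0.0212, Timp3 at 0.65 and Anp32e at 0.0027.

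In cluster 11 the neuronal differentiation median was -0.038, astrocyte maturation -0.34 and dissociation and immediate early genes -0.18, with Frzb at 0.23, Lhx9 at 0.96, Id1 at 0.59, Id3 at 0.48, Lef1 at 0.0208 and Ckap5 at -0.0641. In cluster 17 the neuronal differentiation median was 0.0425 and extracellular matrix -0.26, with Kcnk2 at -2.04, Hist1h2ap at -0.0229, Clu at -0.11, Nrarp at -0.50, Dkk3 at 0.15, Bax at 0.0011, Timp2 at -0.47, H2-K1 at -0.41 and H2-D1 at -3.38.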

Other observations

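Cdkn2a, a cell cycle inhibitor gene known as a Polycomb target, was higher in 3 neuron groups of the KO library, with ratio intervals that left out 1. Its neighbour Cdkn2b also had more UMIs in those groups, but only in cluster 1 did the interval leave out 1. Both were singled out after their values were seen. Cdkn2a had 7 control and 44 KO UMIs in cluster 0 (log2 ratio 1.92; ratio interval 1.79 to 10.5), and 10 and 31 in cluster 1 (3.18; 4.46 to 21.4). Pyramidal neuron-like cells, mostly of cluster 8 in the control and cluster 10 in the KO library, had 7 and 28 (1.30; 1.11 to 7.05). Endothelial-like cells had 10 and 2 UMIs, with a ratio interval of 0.0231 to 1.02, and GABAergic neuron-like cells had 2 and 2. Cdkn2b had 0 and 12 UMIs in cluster 1 (ratio interval from 8.37), while the intervals held 1 in cluster 0 (2 and 13 UMIs; 0.937 to 37.8) and in pyramidal neuron-like cells (1 and 9 UMIs; 0.810 to 256). In endothelial-like cells, outside the Cre lineage, Cdkn2b was also higher, with 199 and 233 UMIs (0.34; 1.05 to 1.54). Over all cells Cdkn2a was at 1.63 and Cdkn2b at 0.70, and no explanation was tested.

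Neurod6, a neuronal bHLH gene related to Neurod2, was at -0.04 over all cells, -0.07 in cluster 0, -0.18 in cluster 1, 0.22 in pyramidal neuron-like cells, -0.31 in neuroblast-like cells and -0.76 in intermediate progenitor-like cells.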
